A study of Homo sapiens with 6 samples.

How the data were processed

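SH-SY5Y human neuroblastoma cells were infected with lentivirus carrying a control hairpin or a hairpin against TDP-43 and selected with puromycin at 2 µg/mL for 2 weeks, per the labels' protocols. Total RNA was extracted with TRIzol, poly(A) RNA was isolated, and directional libraries were prepared, per the labels' protocols. Each group, shNC and shTDP43, had 3 libraries, numbered as in the labels.

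The authors deposited a table with an FPKM value for each of 26372 gene symbols in each of the 6 libraries. TopHat2 2.1.0, SAMtools and Cuffdiff 2.2.1 and genome build hg38 are named per the submitters' processing notes. The gene annotation, the use of strand, the treatment of reads with several matches and the scaling between libraries are not given in the sources used here. Because the table holds no counts, count models were not used and the absolute depth is unknown. The FPKM of a library summed to between 908329 and 1592930, while the upper quartile was between 10.5 and 10.7 FPKM in each library. The sums follow a few short structural RNAs, whose FPKM is inflated by their small length, and are no measure of depth. Relative depth was estimated from 1655 genes above 0 in all 6 libraries with a mean under 0.3 FPKM, as the inverse of the most frequent ratio of a gene's value to that in shTDP43 replicate 1, since a read is worth a higher FPKM in a library of lower depth. Between 5.92% and 9.79% of these genes lay at that ratio within 0.01 on the log2 scale, so the estimate is rough. No pair of libraries held identical values, and at most 0.0905% of tested genes had values equal to the last deposited digit (no tolerance) in a pair.

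Values were analysed as log2(FPKM + 1) with R 4.3.3 and limma 3.58.1. Genes with a mean of at least 1 FPKM over the 6 libraries were tested (13263 genes), and 13109 genes were below that mean. A linear model with group as its only term was fitted, variances were moderated with a trend on expression level, the test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over tested genes. Fold changes on this scale understate the change of genes with low values, so percentages of control and folds are ratios of mean FPKM. Means are given with the SD over 3 libraries. For TARDBP an exact permutation test of the 6 values was run as well. No fold is given where a group was listed at 0, since an exact 0 can be a failed estimate.

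Before the data were examined, 22 gene lists were fixed, of which the list of genes on the mitochondrial chromosome had 0 members in the table, so 21 were tested. The lists share 0 tested genes with one another. Each list was compared with the other tested genes by camera in limma, with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the 21 lists. With an estimated correlation, camera also takes its degrees of freedom from the 6 libraries rather than from the number of genes. The fry test of limma was run as a self-contained test. Counts of members past the threshold are given over all tested genes and adjusted over the list alone.

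Genes to name were also fixed by a rule before the data were examined. The rule took TARDBP, STMN2 and UNC13A, then the 6 largest rises and 6 largest falls among genes past the threshold whose groups did not overlap, and then the 2 members of each list that passed with the largest change. Because several of these were listed at 0 in a group, the 10 largest rises and 10 largest falls among protein-coding genes above 0 in all 6 libraries were added after their values were seen. Further list members, the structural RNAs, MALAT1, the neighbours of FGF14 and the genes of families grouped by symbol were chosen after their values were seen. Some genes, among them a member that the rule takes, are not reported here.

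Gene locations and types came from NCBI's RefSeq annotation of GRCh38, the assembly that hg38 also names. Of the symbols, 23643 matched a current symbol and 1563 an older one (95.6%). Transcript length and GC content for a correction came from the longest GENCODE transcript of each gene. Overlapping and antisense genes, read-through transcripts and near-identical copies are named as uncertain, because the counting is not described.

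The test was checked on simulated data for shTDP43 against shNC with the real genes' levels and spreads (13263 genes, of which 200 were changed). It recovered 24 of 50 genes changed 1.2-fold, 44 of 50 changed 1.5-fold, 49 of 50 changed 2-fold and 50 of 50 changed 3-fold, and called 9 unchanged genes. In a separate simulated data set, a list of 30 genes moved by 0.2 on the log2 scale gave a camera p of 1.31e-34, and an unmoved list 0.287. The simulated genes varied independently of one another, so this check does not cover lists of correlated genes. No gene outside the moved list was changed there, unlike in the real data, so its p-values do not measure the power of camera here.

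Alternatives covered the pseudocount, the filter on low values, TMM-type scaling, median centring, quantile normalization, variance moderation without a trend or with robust weights, library weights, the replicate number as a block, leaving out each library in turn, a stricter threshold, a test against a fold of 2, and camera on ranks. The TMM-type factors were computed on FPKM with 30% and 5% trims. Added after seeing the data were genes above 0 in all libraries, protein-coding genes alone, leaving out both libraries with low SNORD3A, and a correction of each library for transcript length and GC content with splines of 4 degrees of freedom. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.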

Results

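RNA was measured in SH-SY5Y cells, a human neuroblastoma line with neuron-like features, that carried a lentiviral short hairpin RNA. A control hairpin (shNC) was compared with a hairpin against TDP-43 (shTDP43), the DNA- and RNA-binding protein encoded by TARDBP that is lost from the nucleus of neurons in most cases of amyotrophic lateral sclerosis. Each group had 3 libraries of RNA that the labels describe as poly(A)-selected. Each library gave an FPKM value (fragments per kilobase of gene, scaled to the size of the library) for 26372 gene symbols. The labels do not say whether the 3 libraries of a group came from separate infections or cultures, so the p-values below measure only the spread between these samples, which may be technical. Between 18217 and 18334 genes were above 0 in an shNC library, and between 17945 and 18025 in an shTDP43 library. The values hold no read totals. Steps among the lowest values gave relative depths of 1.28, 1.27 and 1.16 for the shNC libraries and 1, 1.11 and 1.1 for the shTDP43 libraries. Estimated depth and the number of genes above 0 were thus higher in each shNC library than in each shTDP43 library. For genes near 0, depth and group cannot be told apart. Libraries of the same group correlated at r = 0.993 to 0.995 across genes on the log2 scale, and libraries of different groups at r = 0.980 to 0.982. The first principal component, with 61.6% of the variance, separated the groups.

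The comparison asks how gene expression differs in cells that stably carry a hairpin against TDP-43. TDP-43 protein was not analysed here. The samples hold no other hairpin against TDP-43 and no rescue. Other effects of the hairpin, or a difference between the infected populations, therefore cannot be told apart from an effect of TDP-43. TARDBP itself (GRCh38 chromosome 1, 11012654 to 11030528) fell from 56.3 ± 0.288 FPKM in shNC to 34.6 ± 1.43 FPKM in shTDP43 (SD, n = 3 each), which is 61.5% of the control level. The log2 fold change was -0.69 (SE 0.03; limma adjusted p = 2.84e-06), and each of the 3 shTDP43 libraries lay below each shNC library. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries can reach.

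STMN2 (chromosome 8, 79611117 to 79666158), which encodes the axonal growth protein stathmin-2 and whose message is truncated when TDP-43 is lost, fell from 678 ± 6.00 to 289.9 ± 0.484 FPKM (SD, n = 3), 42.8% of control. Its log2 fold change was -1.22 (SE 0.02; limma adjusted p = 8.19e-09). SYT7 (chromosome 11, 61513714 to 61588387), a synaptotagmin of vesicle release, fell from 12.3 ± 0.291 to 5.41 ± 0.429 FPKM, 43.8% of control (limma adjusted p = 5.45e-06). UNC13A (chromosome 19, 17601336 to 17688354), a synaptic vesicle priming gene that gains a cryptic exon without TDP-43, did not pass the test. It stood at 15.2 ± 0.353 FPKM in shNC and 16.3 ± 0.460 FPKM in shTDP43, a log2 difference of 0.09 (95% interval 0.01 to 0.17; limma adjusted p = 0.0768). Adjusted over the list of TDP-43 target transcripts alone it passed as higher (limma adjusted p = 0.0484). Splicing within UNC13A or STMN2 was not analysed here, since the values are sums per gene.

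That list holds genes reported to lose normal splicing, polyadenylation or mRNA level without TDP-43, so a fall is part of how it was chosen. Of its 26 tested members 12 fell and 4 rose (13 and 5 adjusted over the list alone, UNC13A among the 5). The number higher was 2 without shNC replicate 3, without shTDP43 replicate 2, or without both libraries low in the small nucleolar RNA SNORD3A (shNC replicate 1 and shTDP43 replicate 3). Besides STMN2 and SYT7, the matrix protein gene AGRN fell to 61.7% of control, the glycolytic enzyme gene PFKP to 64.9%, the insulin receptor gene INSR to 71.1% and the neuronal RNA-binding protein gene ELAVL3 to 73.4%. Those that rose included CELF5 at 113% of control, RSF1 at 109.7% and HDGFRP2 at 109.6%. The median log2 fold change was -0.10. The list lay lower than other genes by camera with a preset correlation (adjusted p = 0.00794), and the adjusted p was 0.187 with an estimated correlation.

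**Figure D1:**
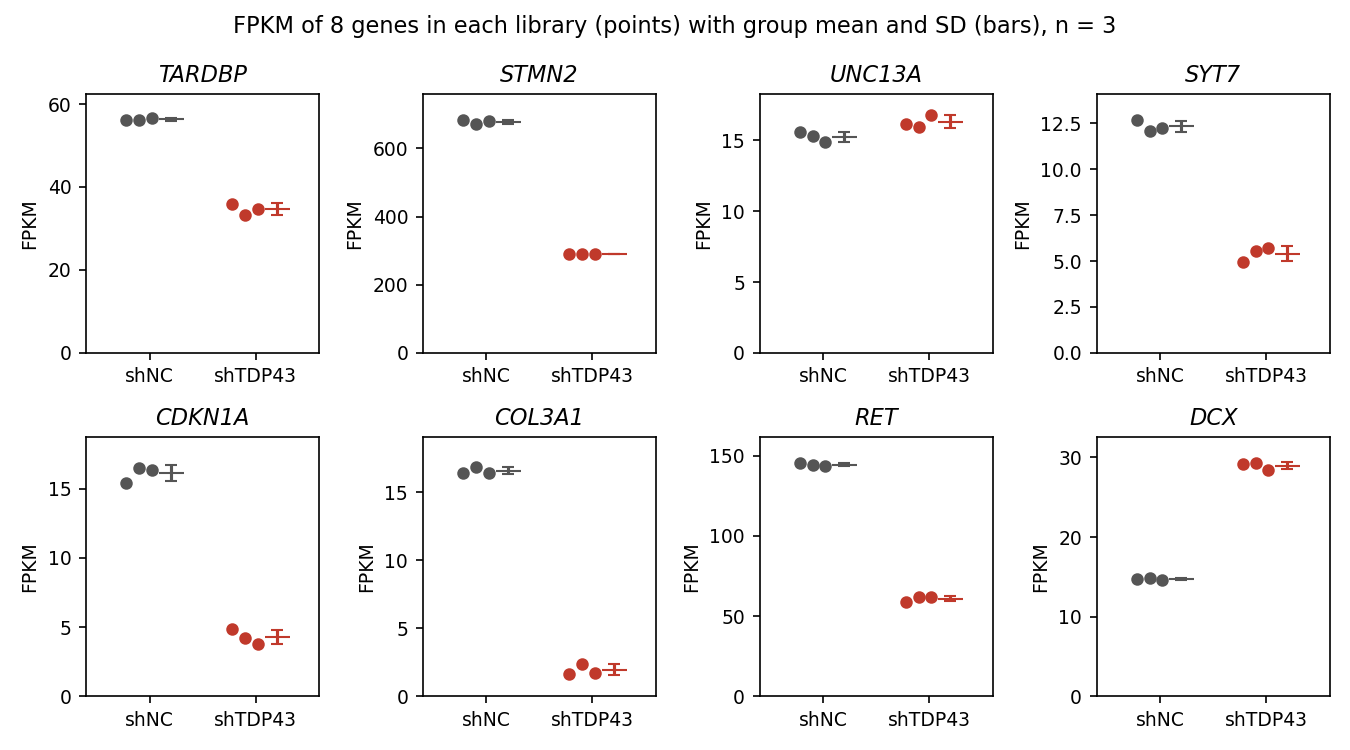
FPKM of 8 genes in each library (points), with the group mean and SD beside them (n = 3 shNC in grey and 3 shTDP43 in red; vertical axes in FPKM, starting at 0). TARDBP ran from 56.1 to 56.6 FPKM in shNC and from 33.1 to 36.0 FPKM in shTDP43, STMN2, SYT7, CDKN1A, COL3A1 and RET were lower in each shTDP43 library than in each shNC library, DCX was higher, and UNC13A ran from 14.9 to 15.6 FPKM in shNC and from 15.9 to 16.8 FPKM in shTDP43.

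The largest rises among protein-coding genes above 0 in every library included SLITRK6, VSNL1 and GFRA3. SLITRK6 (chromosome 13, 85792790 to 85799419), a neuronal transmembrane protein gene, rose 5.04-fold, from 6.95 ± 0.129 to 35.0 ± 0.308 FPKM (SD, n = 3; limma adjusted p = 3.17e-09). VSNL1, a neuronal calcium sensor gene, rose 6.00-fold from 1.77 ± 0.369 to 10.6 ± 0.955 FPKM. GFRA3, a receptor gene for artemin, rose 4.13-fold to 18.9 ± 0.25 FPKM, and the glutamate receptor gene GRM8 rose 3.34-fold to 24.0 ± 0.313 FPKM. PRICKLE1, a planar cell polarity gene, rose 3.16-fold to 41.0 ± 1.5 FPKM. CNTNAP4, KIAA1324, FUT9, FGF7 and ZMAT4 completed the 10 largest rises, at 6.97, 4.45, 4.07, 3.63 and 4.09 times the control level. Rises and falls were ranked on the log2(FPKM + 1) scale, whereas the folds are ratios of mean FPKM, by which CNTNAP4 rose most among these 10.

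The largest falls among such genes included COL3A1, IGFBP3 and SLC27A6. COL3A1 (chromosome 2, 188974373 to 189012746), a fibrillar collagen gene, fell from 16.6 ± 0.246 to 1.93 ± 0.405 FPKM (SD, n = 3), 11.7% of control, with a log2 fold change of -2.59 (SE 0.09; limma adjusted p = 4.41e-07). IGFBP3, which encodes a carrier of insulin-like growth factors, fell from 8.43 ± 0.352 to 1.64 ± 0.165 FPKM, 19.4% of control. SLC27A6, a fatty acid transporter gene, fell to 16.7% and ACTA2, a smooth muscle actin gene, to 17.0% of control. CLU, the gene for the secreted chaperone clusterin, fell to 21.5%, the cell cycle inhibitor gene CDKN1A to 26.6% and the neuropeptide gene VIP to 27.0%. ANXA2 fell to 28.9%, AHNAK to 29.95% and the secretory granule gene CHGB to 33.6%, from 375 ± 10.1 to 126 ± 3.32 FPKM. The log2(FPKM + 1) scale understates such changes in genes of low level.

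In all, 5054 of 13263 tested genes (38.1%) passed a limma adjusted p under 0.05, with 2448 higher and 2606 lower in shTDP43. Most changes were small, with 4438 of the 5054 (87.8%) under 0.5 in log2 size and a median size of 0.24. At least 2-fold changes were found in 114 genes, of which 83 fell and 31 rose. The groups did not overlap in 6724 genes (50.7%), against 10% given by chance for 3 against 3. The count of 2-fold changes was 218 with a pseudocount of 0.1, 232 with a pseudocount of 0.01, and 58 among genes with a mean of at least 5 FPKM. The count of 5054 fell to 3323 when both low-SNORD3A libraries were left out, which leaves fewer libraries for the test, here and below.

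**Figure D2:**
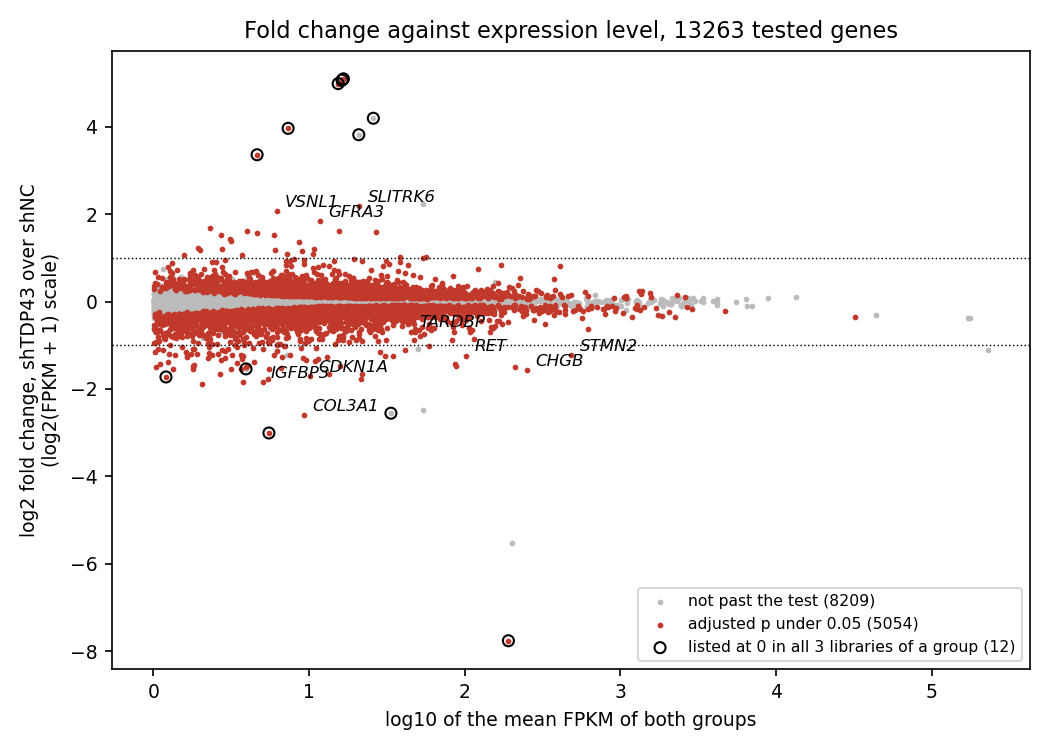
Log2 fold change of shTDP43 over shNC (vertical axis, log2(FPKM + 1) scale) against the log10 of the mean FPKM of both groups (horizontal axis) for the 13263 tested genes, with those past a limma adjusted p under 0.05 in red, circles around genes listed at 0 in all 3 libraries of a group, and dotted lines at 2-fold. Most of the 5054 genes past the test lie well inside the 2-fold lines, and the highest and the lowest point are genes listed at 0 in a group.

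A locus on the long arm of chromosome 13 stood apart. FGF14, which encodes an intracellular regulator of sodium channels, and the neighbouring integrin-related gene ITGBL1 were listed at 0 in all 3 shNC libraries. In the shTDP43 libraries FGF14 (101710804 to 102402443) had 33.3, 34.7 and 29.6 FPKM and ITGBL1 (101452675 to 101720856) had 9.16, 9.24 and 9.40 FPKM. FGF14-AS2 (33.5, 31.7 and 34.6 FPKM), FGF14-IT1 (31.7, 31.6 and 28.9 FPKM) and FGF14-AS1 (13.7, 16.5 and 13.8 FPKM) lie within FGF14 and were likewise listed at 0 in shNC. Strand use in the counting is not given in the sources used here, so reads of FGF14 and of these overlapping RNAs cannot be separated. An exact 0 can be a failed estimate in such a table, since the abundant nuclear RNA MALAT1 was listed at 0 in all 6 libraries.

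A mean of at least 1 FPKM in a group whose counterpart was at 0 in all 3 libraries was found for 13 genes, 7 of them listed at 0 in shNC and 6 in shTDP43. Those at 0 in shNC were FGF14, ITGBL1, the RNAs within FGF14, and SCARNA1 and SNORA81, each also at 0 in 1 shTDP43 library. Among those at 0 in shTDP43, MIR7851, RNU105B and SNORD3B-2 were above 0 in only 1 shNC library. SNORD3B-1, a copy of the U3 small nucleolar RNA on chromosome 17 (19061912 to 19062128), had 933, 130.3 and 82.1 FPKM in shNC, and the ribosomal RNA gene RNA28S5 had 6.31, 1.72 and 25.1 FPKM. Both were listed at 0 in shTDP43. Both have near-identical copies, so their values are uncertain. The read-through transcript SLMO2-ATP5E, which shares exons with its parent genes and is uncertain for that reason, fell from 3.95 ± 2.72 to 0.161 ± 0.167 FPKM (SD, n = 3; limma adjusted p = 0.0116).

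Markers of the mesenchymal, substrate-adherent type of neuroblastoma cell mostly fell, with 17 of 22 tested members lower and 4 higher (the same counts adjusted over the list alone). Their median log2 fold change was -0.55. It was -0.35 among genes of at least 5 FPKM, where 10 of 14 were lower, and -0.36 without a filter on low values. Next to COL3A1 and ANXA2, the actin-binding protein gene TAGLN fell to 29.6% of control, the receptor gene CD44 to 41.3%, the galectin gene LGALS1 to 61.1% and the intermediate filament gene VIM to 65.8%. The 4 that rose were TNC, a matrix protein gene, at 184% of control, the transcription factor genes TWIST1 at 145% and FOSL2 at 117%, and the receptor gene PDGFRB at 122.6%. The list lay lower than other genes by camera (adjusted p = 1.63e-05), and the adjusted p was 0.166 with an estimated correlation. Of 19 Schwann cell and glial markers 5 were tested. PMP22, a myelin protein gene, fell to 36.5% of control, S100B to 51.5% and the receptor gene ERBB2 fell as well, which makes 3 members lower and 0 higher (the same adjusted over the list alone; camera adjusted p = 0.107). The median of these few genes was -0.37, but 0.07 without shNC replicate 3 (3 of 7 lower and 1 higher), -0.15 without shNC replicate 1, -0.21 without shNC replicate 2 and -0.17 without shTDP43 replicate 1, and the camera adjusted p ran from 0.0599 to 0.615 without each library in turn. Without a filter on low values the median was 0.02, and 1 member was lower without both low-SNORD3A libraries. Of 21 blood, endothelial and epithelial markers, 2 reached the level tested. KRT18, a keratin gene, fell from 2.17 ± 0.544 to 0.368 ± 0.208 FPKM (SD, n = 3), while EPCAM had 0.984 ± 0.294 and 1.03 ± 0.249 FPKM (camera adjusted p = 0.326; 1 lower and 0 higher adjusted over the list alone).

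Genes of the noradrenergic, neuroblast-type state moved in both directions, with 14 of 27 tested members higher and 9 lower (the same adjusted over the list alone). RET, the receptor tyrosine kinase gene, fell from 144 ± 0.881 to 60.9 ± 1.73 FPKM (SD, n = 3), 42.1% of control, and CHGB fell beside it. CHGA, which encodes the related granule protein chromogranin A, rose from 296 ± 5.09 to 520.1 ± 8.04 FPKM, 175% of control. The transcription factor genes SOX11 and TFAP2B rose to 167% and 135%, whereas PHOX2A fell to 80.1%. The median of the list was 0.06 (0.12 with quantile normalization), its mean -0.02, and camera did not find it different from other genes (direction higher, adjusted p = 0.272).

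Synaptic and axonal genes were lower in 16 of 40 tested members and higher in 7 (16 and 8 adjusted over the list alone). SYT4, a vesicle protein gene, fell from 107 ± 1.55 to 58.3 ± 1.48 FPKM (SD, n = 3), 54.4% of control, ELAVL4 fell to 66.6% and the growth cone gene GAP43 to 74.3%. DCX, a microtubule-binding protein gene of migrating neurons, rose 1.96-fold to 28.95 ± 0.443 FPKM, and the glutamate receptor gene GRIA2 rose to 191% of control. The median was -0.06 (camera adjusted p = 0.0453, and adjusted p = 0.426 with an estimated correlation), and the call was lost without shNC replicate 1, shNC replicate 2 or shTDP43 replicate 1, with adjusted p values of up to 0.0801.

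Targets of the tumour suppressor p53 fell, with 16 of 24 tested members lower and 0 higher (the same adjusted over the list alone). CDKN1A, which encodes the cell cycle inhibitor p21, fell from 16.1 ± 0.582 to 4.28 ± 0.527 FPKM (SD, n = 3). TNFRSF10B, a death receptor gene, fell to 51.9% of control, the DNA repair gene DDB2 to 51.9% and the ribonucleotide reductase gene RRM2B to 53.02%, whereas MDM2, the p53 ubiquitin ligase gene, fell to 91.5%. The median was -0.29 (camera adjusted p = 5.14e-06), and the adjusted p was 0.0967 with an estimated correlation, the lowest such value of the lists. Proliferation genes did not pass as a group. In that list 12 of 37 fell, CDT1 to 78.4% and CENPE to 82.5% of control among them, and 7 rose (the same adjusted over the list alone; camera adjusted p = 0.618), and 7 were lower without both low-SNORD3A libraries.

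Factors that resolve or prevent R-loops, which are RNA-DNA hybrids with a displaced DNA strand, were higher in 14 of 36 tested members and lower in 2 (15 and 2 adjusted over the list alone). THOC1, a subunit of the mRNA export complex THO, rose to 133% of control, the helicase gene DHX9 to 128% (from 90.5 ± 1.07 to 116 ± 0.590 FPKM; SD, n = 3) and the topoisomerase gene TOP1 to 126%. FANCD2 and THOC7 fell to 91.4% and 92.0%. RNASEH1, the gene for an RNase that cuts such hybrids, had 101% of control and did not pass the test (limma adjusted p = 0.585). The median was 0.09 (camera adjusted p = 0.00080, and adjusted p = 0.187 with an estimated correlation). It was 0.06 without shNC replicate 2, where 12 were higher and 0 lower, and 0.06 after a correction for transcript length and GC content.

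Enzymes and readers of DNA methylation and hydroxymethylation were higher in 9 of 26 tested members and lower in 1 (9 and 2 adjusted over the list alone). TET3, which oxidises 5-methylcytosine to 5-hydroxymethylcytosine, rose to 134% of control, from 11.4 ± 0.322 to 15.3 ± 0.331 FPKM (SD, n = 3), and DNMT3A, a methyltransferase gene, rose to 118%. GADD45G rose to 158% and CXXC5 fell to 80.6%. TET1 at 95.6% and TET2 at 102% of control did not pass the test (limma adjusted p = 0.124 and 0.70). The list median was 0.08 (camera adjusted p = 0.0453, and adjusted p = 0.204 with an estimated correlation), and the call was lost without shNC replicate 1, shNC replicate 3, shTDP43 replicate 1 or shTDP43 replicate 2, with adjusted p values of up to 0.0616. Levels of R-loops, hydroxymethylcytosine and transposable elements were not analysed here.

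Factors that silence or restrict transposable elements were higher in 11 of 27 tested members and lower in 2 (12 and 2 adjusted over the list alone). SUV39H1, a histone H3 methyltransferase gene, rose to 145% of control, SETDB1 to 111% and the corepressor gene TRIM28 to 107%. The 2 that fell were restriction factor genes, APOBEC3C at 65.5% and MOV10 at 79.3% of control. The median was 0.07 (camera adjusted p = 0.00699, and adjusted p = 0.202 with an estimated correlation), and 6 members were higher without both low-SNORD3A libraries. Of 504 tested genes with a ZNF symbol, 467 are annotated as protein-coding (129 higher and 40 lower), 17 are antisense RNAs and 20 are pseudogenes. Many zinc finger proteins with a ZNF symbol repress transposable elements through TRIM28. Of all 504, 134 were higher and 45 lower (132 and 45 adjusted over the list alone), with a median of 0.06 (camera adjusted p = 0.00592, and adjusted p = 0.187 with an estimated correlation). Without both low-SNORD3A libraries 85 were higher and 29 lower. The strongest changes in that group went the other way, with ZNF676 at 25.0% and ZNF728 at 21.5% of control.

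Of 51 nucleic acid sensors and interferon-responsive genes, 19 were high enough to test, of which 7 fell and 1 rose (8 and 1 adjusted over the list alone). HLA-C, a class I antigen presentation gene, fell from 8.91 ± 1.04 to 3.50 ± 0.492 FPKM (SD, n = 3), 39.3% of control. PSMB8, an immunoproteasome gene, fell to 30.6%, BST2 to 40.9% and B2M to 71.3% of control, while IFIT5 rose to 120%. HLA genes are near-identical in part, so the split of reads between them is uncertain. The median was -0.11 (camera adjusted p = 0.0453, and adjusted p = 0.192 with an estimated correlation), and the call was lost without shNC replicate 1 or shNC replicate 3, with adjusted p values of up to 0.110. The median was -0.07 without shNC replicate 3 and -0.06 with quantile normalization. Without a filter on low values it was -0.07 over 48 genes, of which 13 were lower and 2 higher.

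Cholesterol synthesis and uptake genes were higher in 10 of 27 tested members and lower in 1 (11 and 1 adjusted over the list alone). The isomerase gene IDI1 rose to 139.0% of control and SQLE, which encodes the squalene epoxidase of sterol synthesis, to 136%, and SREBF1 fell to 81.2%. The median was 0.07 (camera adjusted p = 0.00794, and adjusted p = 0.187 with an estimated correlation). Nuclear-encoded subunits of the respiratory chain were lower in 15 of 35 members and higher in 2 (the same adjusted over the list alone). UQCRFS1 fell to 83.3%, COX6C to 83.8% and COX7C to 86.6% of control, and SDHD and NDUFV1 rose to 113% and 108%. The median there was -0.09 (camera adjusted p = 0.00080, and adjusted p = 0.187 with an estimated correlation), with 9 members lower without both low-SNORD3A libraries and 0 higher without shNC replicate 1, shNC replicate 3 or shTDP43 replicate 1.

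Genes of glycolysis and hypoxia did not pass as a group (5 of 27 higher and 9 lower, 6 and 10 adjusted over the list alone; camera adjusted p = 0.272). Without both low-SNORD3A libraries 3 were higher and 3 lower, and 3 were higher without shTDP43 replicate 2 or shTDP43 replicate 3. ADM, the gene for the peptide hormone adrenomedullin, rose 2.45-fold to 12.7 ± 0.487 FPKM (SD, n = 3) and PFKFB3 fell to 75.2% of control. Integrated stress and unfolded protein response genes were lower in 10 of 27 members and higher in 5 (the same adjusted over the list alone; camera adjusted p = 0.111). The stress-induced transcription factor genes ATF3 and ATF4 fell to 60.1% and 82.5% of control and EDEM1 to 66.0%, while the chaperone gene HSPA5 rose to 111%. Genes tied to amyotrophic lateral sclerosis or frontotemporal dementia were higher in 8 and lower in 7 of 31 members (the same adjusted over the list alone). ANXA11 fell to 68.4% and the autophagy receptor gene OPTN to 67.3%, and the RNA-binding protein gene MATR3 rose to 112% of control. The median of that list was -0.01 while camera's direction was higher (adjusted p = 0.669). The median was 0.00 and above 0 with TMM-type scaling, 0.01 without shNC replicate 2, 0.02 without shTDP43 replicate 3, 0.03 without both low-SNORD3A libraries and -0.02 without shTDP43 replicate 2.

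Members of the list of replication-dependent histone genes were lower in 28 of 60 tested and higher in 3 (30 and 3 adjusted over the list alone), with HIST1H4K at 69.3% and HIST2H2BA, annotated as a transcribed pseudogene, at 71.7% of control. Of the 60, 53 are annotated as protein-coding (24 lower) and 2 as pseudogenes, and 5 had no annotated type here. The median was -0.13 (camera adjusted p = 1.63e-05, and adjusted p = 0.287 with an estimated correlation). With quantile normalization 18 were lower and 4 higher, with a median of -0.07. Histone mRNAs mostly lack poly(A) tails, as do most structural RNAs, of which 9 of 36 tested genes passed as lower and 0 as higher, with no test of the group. Both kinds were high in shNC, with HIST1H4C at 2226 ± 80.3 FPKM and RN7SL1 at 195040 ± 15971 FPKM (SD, n = 3). ACTB had 1045 to 1084 FPKM there. The FPKM of short RNAs is inflated, so how far poly(A) selection removed such RNA is unknown. RPPH1 fell to 77.7% of control (limma adjusted p = 0.0128), and RN7SL1 at 77.2%, RN7SL2 at 77.1% and RMRP at 80.8% did not pass the test. With SNORD3A these took between 42.5% and 66.7% of a library's summed FPKM. SNORD3A had 11541 FPKM in shNC replicate 1 and 8551 FPKM in shTDP43 replicate 3, against 137209 to 552747 FPKM in the other 4 libraries. The call for histone genes was lost after a correction for transcript length and GC content (adjusted p = 0.129), with 13 lower. Many histone genes are near-identical copies, and the split of reads between them is uncertain.

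Clustered protocadherin genes, which encode adhesion proteins of neuronal identity, were lower in 11 of 43 tested members and higher in 1 (7 and 0 adjusted over the list alone). The number lower was 3 without shNC replicate 1, 5 without shNC replicate 2 or shTDP43 replicate 2, 6 without shTDP43 replicate 1, 7 without shTDP43 replicate 3 and 1 without both low-SNORD3A libraries. PCDHB13 fell to 67.3% and PCDHAC1 to 72.1% of control, and both are uncertain because members share exons or near-identical sequence. The median was -0.14 (camera adjusted p = 0.0208, and adjusted p = 0.254 with an estimated correlation). The call was lost with quantile normalization (camera adjusted p = 0.0944, median -0.09) and among genes of at least 5 FPKM (0.0533, median -0.14). Cytosolic ribosomal protein genes did not pass as a group, with 13 of 82 higher and 12 lower (11 and 8 adjusted over the list alone), a median of 0.00 and a mean of -0.01 (camera direction higher, adjusted p = 0.860). With quantile normalization 17 were higher and 6 lower, with a median of 0.03, and with TMM-type scaling 15 and 9. Without shNC replicate 2, shTDP43 replicate 1 or shTDP43 replicate 2 there were 8 higher, without shTDP43 replicate 3 there were 8 lower, without both low-SNORD3A libraries 9 were higher and 6 lower, and the median was -0.01 without shNC replicate 3 or shTDP43 replicate 1. RPL39L at 55.3% and RPS27L at 62.8% of control fell most.

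**Figure D3:**
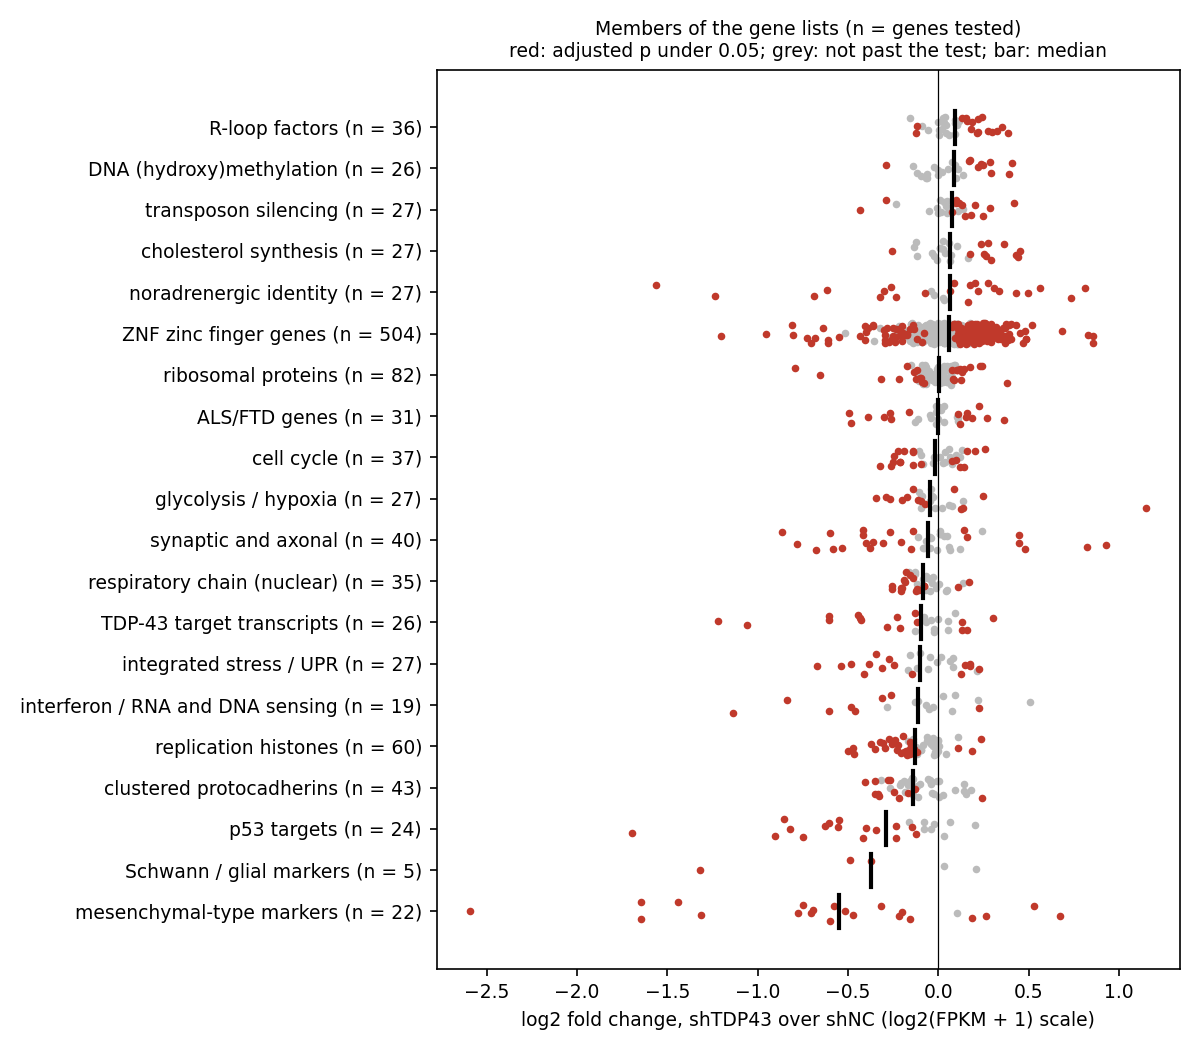
Log2 fold change of shTDP43 over shNC (horizontal axis, log2(FPKM + 1) scale) for each tested member of 20 gene lists, ordered by list median (black bar), with genes past a limma adjusted p under 0.05 in red and the others in grey. The mesenchymal-type markers (median -0.55) and p53 targets (median -0.29) lie left of 0, whereas R-loop factors (median 0.09) lie slightly right of it.

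In all, 13 of 21 tested lists passed camera with a preset correlation, 5 of them higher and 8 lower, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. The fry test, which asks whether a list's genes move on balance in 1 direction and compares them with no other genes, gave an adjusted p under 0.05 for 16 of the 21 lists. Genomic gene length had a Spearman correlation of -0.02 with the log2 fold change across 11908 protein-coding genes, which are not independent replicates. In the fifth of these genes with the longest loci 660 fell and 484 rose, with a median of -0.02, and in the fifth with the shortest 477 fell and 386 rose, with a median of -0.01.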

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

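The settings without low-SNORD3A libraries, with the length and GC correction, and with genes above 0 in all libraries or protein-coding genes alone were chosen only after the results were seen; the others were planned. The fall of TARDBP kept its direction and passed in all alternatives run (log2 fold change -0.71 to -0.65). The count of 5054 changed genes stayed within 1.5 times except at adjusted p under 0.01 (2941) and without both low-SNORD3A libraries (3323), a fit with fewer samples; without each library in turn it was 4009 to 4385. The count of 114 2-fold changes was 218 and 232 with pseudocounts of 0.1 and 0.01, which enlarge the log2 change of low genes, 58 among genes of at least 5 FPKM, which tests fewer genes, 40 in a test against a fold of 2, and 110 to 126 without each library in turn. Genes listed at 0 in a group numbered 134 instead of 13 with a minimum of 0.1 FPKM in the other group, 56 of them at 0 in shNC and 78 in shTDP43. Scaling left the split of calls near even (48.4% higher, 53.1% with quantile normalization).

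For gene lists, 433 of 477 alternatives gave the same direction and side of the threshold. With an estimated correlation 0 of 13 calls held: adjusted p was 0.0967 for p53 targets, 0.166 for mesenchymal-type markers, 0.187 for TDP-43 target transcripts, R-loop factors, cholesterol synthesis, the respiratory chain and ZNF genes, 0.192 for interferon genes, 0.202 for transposon silencing, 0.204 for DNA methylation, 0.254 for protocadherins, 0.287 for histones and 0.426 for synaptic genes. The estimated correlation was -0.0302 for p53 targets, -0.0128 for interferon genes, 0.0103 for ZNF genes and 0.0121 for DNA methylation, against the preset 0.01. Being near or below the preset, it cannot by itself account for the loss of these calls. For ZNF genes, at nearly the same correlation, the camera adjusted p still went from 0.00592 to 0.187. The settings thus differ in more than the correlation, namely in the degrees of freedom as well. A lost call is therefore no sign by itself that genes of a list are correlated. For the other called lists the estimated correlation was higher, up to 0.191 for histones. Apart from the setting with an estimated correlation 8 of the 13 kept their calls. Calls were also lost, with these adjusted p values and a cause that was not tested: at 5 FPKM or more for DNA methylation (0.117) and protocadherins (0.0533); with quantile normalization for the same lists (0.0944 each) and interferon genes (0.0512); with median centring for synaptic genes (0.0501); on ranks for DNA methylation (0.0676), interferon (0.0604) and synaptic genes (0.113); without low-SNORD3A libraries for interferon genes (0.0634); with the length and GC correction for DNA methylation and synaptic genes (0.0573 each) and interferon genes (0.0516). The same correction ended the call of histones (0.129), whose median shrank to -0.06. Without each library in turn, p ran from 0.0235 to 0.0616 for DNA methylation (lost without shNC 1, shNC 3, shTDP43 1 or shTDP43 2), 0.00713 to 0.110 for interferon genes (lost without shNC 1 or 3), 0.0369 to 0.0801 for synaptic genes (lost without shNC 1, shNC 2 or shTDP43 1) and 0.507 to 0.891 for ribosomal proteins, whose direction turned without shNC 2, shNC 3 or shTDP43 1 and at 5 FPKM or more (0.849). Schwann and glial markers turned without the filter (0.760). These 2 lists were not called in any case.

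With the replicate number as a block, 4502 genes and 117 2-fold changes were called, and DNA methylation and synaptic genes (0.0680 each) and interferon genes (0.0504) were lost. The numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.07, 0.06 and 0.11, and 1 of 3 pairs correlated best with its own number. Of 1345 alternatives for named genes 1315 were the same, 30 ended the call (PCDHAC1 8, HIST1H4K 6, PCDHB13 6, GADD45G 3, S100B 3, RNA28S5 2, APOBEC3C 1, SLMO2-ATP5E 1) and 0 reversed. The absolute depth is unknown, so no counting limit can be given for genes listed at 0.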

Other observations

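The grouping of genes by the start of their symbol and the tests of a failed estimate, of carry-over and of the share of mesenchymal-type cells were chosen only after the results they bear on were seen. Genes were grouped into 152 sets by symbol start, of which 11 passed camera in limma with a preset correlation (adjusted p of 0.000314 to 0.0338, HIST and ZNF included). With an estimated correlation 0 passed, 8 had an unadjusted p under 0.05, and the adjusted p was 0.607 or 0.624 for each of the 11. The median of each of the 11 kept its sign under the 3 other scalings, though that of HIST went from -0.14 to -0.07 with quantile normalization. Without both low-SNORD3A libraries, a fit with fewer samples, fewer members passed, with PRPF at 6 higher, RBM at 8 higher, KDM at 4 higher, SMAD at 2 lower and ATP at 17 lower. The medians of these sets stayed close, at 0.15 for PRPF, 0.10 for RBM, 0.10 for KDM, -0.17 for SMAD and -0.08 for ATP. Among the 37 tested genes whose symbol starts with DDX, mostly RNA helicases, 21 rose and 0 fell, with DDX46 at 125% of control (log2 fold change 0.31, SE 0.02), DDX27 at 119% and DDX5 at 109% (n = 3 per group). Of 12 SRSF genes, which encode serine- and arginine-rich splicing factors, 9 rose and 0 fell, SRSF10 to 122% and SRSF2 to 121% of control among them. Of 13 PRPF pre-mRNA processing factor genes 10 rose, PRPF38B to 128% and PRPF8 to 116%, and PRPF40B fell to 84.3%. Genes with an RBM symbol, 33 of them protein-coding and mostly for RNA-binding proteins and 3 antisense RNAs, were higher in 15 of 36 and lower in 0. Genes with a KDM symbol, 17 for histone lysine demethylases and 1 antisense RNA, were higher in 10 of 18 and lower in 0, with KDM5A at 121%. The KDM count was 5 without shNC replicate 1 or shTDP43 replicate 3 and 4 without shTDP43 replicate 2.

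Genes with a COX symbol, mostly subunits and assembly factors of cytochrome c oxidase, were lower in 14 of 22 and higher in 1, the antisense RNA COX10-AS1, with COX7B at 75.2% of control and COX14 at 82.7%. ADAMTS genes, for secreted proteases of the matrix and their antisense RNAs, were lower in 9 of 15 and higher in 3, with ADAMTS19 at 36.4%, ADAMTS5 at 48.6% and ADAMTS1 at 63.5% of control, and ADAMTS17 at 154%. The number of ADAMTS genes higher was 0 without shNC replicate 3 and 1 without any of the shTDP43 replicates in turn. Genes with a SMAD symbol were lower in 5 of 10 and higher in 0. The 8 that encode proteins of TGF-beta and BMP signalling, inhibitors included, were lower in 4. Among these were SMAD1 at 65.4% and the inhibitory SMAD6 at 59.9% of control. The fifth lower gene was the antisense RNA SMAD5-AS1. ATP genes, which mix ion pumps, subunits of ATP synthase and 5 antisense RNAs, were lower in 26 of 68 and higher in 8 (5 higher without shNC replicate 2 or shTDP43 replicate 1), with ATP11A at 64.7% of control.

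The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5054 changed genes and 114 2-fold changes against at most 1 in any other split for either count, so 1 of 10 splits gave as many. For gene lists the real split gave 13 calls and the highest other split 8, again 1 of 10 with as many. The preset correlation called up to 8 lists where the groups were mixed. Each mixed split is uneven and keeps part of the group difference, so these calls need not be false. The group difference also widens the spread within mixed groups, which lowers the gene counts there. The size of the correlation of gene length with fold change was 0.02 in the real split and as high as 0.0852 in another, and 7 of 10 splits gave one as large.

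FGF14 and ITGBL1, listed at 0 in every shNC library, were set against 2 technical explanations. A gain in copy number in shTDP43 reaching neighbouring genes is argued against by the 25 tested genes within 5 Mb on either side. Their median log2 fold change was 0.010, with 5 higher and 6 lower. The locus itself was left out, so a gain or loss of copies confined to it in either group was not tested. A failed estimate of the locus in shNC cannot be told apart from absent expression: 13.5% of protein-coding genes of over 100 kb with a mean under 0.1 FPKM in shNC and above 0 in some library (54 of 401) are listed at exactly 0 in all 3 shNC libraries, so an exact 0 does not decide. A change of the locus by the knockdown, or a difference between the cell populations that were infected, may also account for it and was not tested.

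The lower replication-dependent histone genes were set against 2 technical explanations. After correction for transcript length and GC content the median of the 60 genes went from -0.13 (quartiles -0.19 and -0.03) to -0.061 (quartiles -0.16 and 0.04), with 13 instead of 28 members lower. The call ended with this smaller median and wider spread. Less carry-over of RNA without a poly(A) tail in the shTDP43 libraries is a candidate explanation too, since 36 structural RNA genes had a median log2 fold change of -0.19, with 28 below 0, 9 past the test as lower and 0 as higher. Both remain open, and an effect of the knockdown on histone genes was not tested apart from them.

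The mesenchymal-type markers that fell were set against 2 technical explanations. The scaling of the libraries is argued against, since the list's median kept at least 0.943 of its size under the 3 other scalings. A lower share of mesenchymal-type cells in the shTDP43 culture would lower such markers alike, and 17 fell while 4 rose (TNC, TWIST1, PDGFRB and FOSL2). As those 4 may also be expressed by the neuroblast-type cells, the count leaves open whether the share of cells or expression within cells differed. A change within cells caused by the knockdown is the alternative the design names, and it was not tested separately.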
